A study of Drosophila melanogaster with 3 samples.

How the data were processed

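DNA of the fly cell line ML-DmBG3-c2 was hybridised to 3 Agilent tiling arrays with 2 dyes each, and each array compared an early and a late BrdU-labelled population. Per the labels' protocols, cells of both populations were treated with 1 mM hydroxyurea. The early population received BrdU at 50 µg/ml after 3 h in hydroxyurea, stayed in both for 21 h, and received BrdU again for 1 h after the wash. The late population had 24 h of hydroxyurea, 3 to 4 h without drug and 2 h of BrdU. BrdU-containing DNA was precipitated with an antibody and labelled with Sequenase in the presence of Cy3 or Cy5, per the labels' protocols. All 3 arrays formed 1 group, since each holds both populations.

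The deposited scanner output gives spot brightness as intensity in each dye, from Agilent Feature Extraction 9.5.1.1 per the file headers. The processed intensity is background-subtracted and dye-normalised, per the file headers, which give code 6 for the selection method of the dye normalisation. Whether that normalisation included a loess curve is not given here. The same output holds a log10 ratio of red (Cy5) over green (Cy3), which per the file headers comes from the processed signals. It equalled the ratio of the processed signals within 0.001 at over 99.9% of probes on each array. The authors also deposited a log2 ratio M and a mean log2 signal A for each probe. Per the submitters' processing notes limma was used, with no version given. The authors' deposited M equalled a plain limma loess normalisation within each array of the mean signals, with no background correction, to within 1.9e-14 on every array. It runs as red over green, with medians of -0.01, -0.01 and 0.01 on replicates 1, 2 and 3. A had a Pearson correlation of 1 with the mean log2 of both mean signals on every array.

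Here the main values were log2 ratios of the processed signals, centred on each array's median. No loess was added here, because most probes were taken to carry signal. Control spots (1804 per array) and spots marked as outliers (16, 98 and 69 on replicates 1, 2 and 3) were left out, and saturated spots (6, 5 and 10) were kept. Median processed signals were 1072, 1115 and 1154 in red and 1128, 1139 and 1139 in green. Each ratio was turned by the dye labels, so that channel 1 was the numerator. Channel 1 was Cy3 on replicate 1 and Cy5 on replicates 2 and 3. The labels do not tie a channel to the early or the late population. Probe ratios were averaged in windows of 10 kb with at least 5 probes, which left 12093 windows and removed 710.

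Windows and probes were tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Domains were runs of at least 3 adjacent windows past the threshold with the same sign. Differences between chromosome classes were computed within each array and tested by an exact two-sided sign-flip permutation test over the 3 arrays, whose smallest p is 0.25. Correlation with GC content and the motif classes were tested with 10000 circular shifts of the windows along the genome, which keep their order. Each array is a slide of its own, so slide could not be used as a block. Tables were read with the R package data.table, version 1.17.8, and pictures were drawn with matplotlib in Python.

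Because replicate 2, turned by its dye label, ran against replicates 1 and 3, each result was computed again with this array turned, as an alternative chosen after the data were seen. The smallest number of arrays was turned (1) that gave each pair a correlation above 0. Other choices of design and alternatives were made before the data were examined, unless said otherwise. The correlation with GC content, the motif classes, and the summaries of arm ends, steepest changes, lowest windows and mean signal were not in that plan. The rule for named regions took the 5 longest domains of each direction. The same rule would have named genes, but the probes are placed on FlyBase release 5.1, the gene table used here belongs to another assembly, and the files pair no probe with a gene. The planned tests of gene density and of 22 gene lists were therefore not run, and no gene is named.

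Data were simulated at the spread of these arrays with replicate 2 turned, so they do not show what the test as labelled could find. With 100 windows changed at each size among 12093, the window test found 83% of the windows given a log2 ratio of 1 and 0% of those given 0.25. It made 2 false calls among 11893 unchanged windows. Adjustment is milder where most windows pass. The simulated noise was also independent of the ratio given, while in the data the arrays differed in the size of their ratios. These shares are therefore no limit on the size of the ratios called on the common axis. The probe test found 63.3% of the probes given a log2 ratio of 1, with 17 false calls. Alternatives covered the background correction (normexp with an offset of 50), loess, the authors' deposited ratios, scaling of the arrays, a dye term, dim probes, window size, GC content and leaving out each replicate.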

Results

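Replication timing was measured in ML-DmBG3-c2, a Drosophila melanogaster cell line derived from the central nervous system. Cells in S phase were marked with BrdU, a thymidine analogue that is built into newly copied DNA and can be pulled down with an antibody. An early population was held in 1 mM hydroxyurea, which stalls replication by depleting nucleotides, and took up BrdU during the arrest and for 1 h after release. A late population was arrested for 24 h, released for 3 to 4 h and then given BrdU for 2 h. The precipitated DNA of both populations was labelled with Cy3 or Cy5 and hybridised together to a genome tiling array. The question was which parts of the genome carry more DNA copied early and which carry more DNA copied late. There were 3 arrays of 1 group, numbered as replicates 1, 2 and 3 and listed as separate extractions. The labels do not say whether these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Each array held 241469 probes of 45 to 60 bases with a median spacing of 470 bp. Of these, 99.8%, 99.9% and 99.9% were above background in both dyes on replicates 1, 2 and 3. The number of arrays limits the precision.

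The labels name the dye of each channel but not which channel held the early or the late population. Turned by those dye labels, replicates 1 and 3 ran the same way along the chromosomes and replicate 2 ran against both. Over 12093 windows of 10 kb the ratio of channel 1 to channel 2 had a Pearson correlation of 0.991 between replicates 1 and 3. The correlation was -0.997 between replicates 1 and 2 and -0.995 between replicates 2 and 3. Across single probes it was 0.95, -0.97 and -0.96 for the same pairs. These are correlations across positions within arrays, and neighbouring windows are not independent replicates. The direction of the ratio is therefore not settled, and no region is called early or late here.

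**Figure D1:**
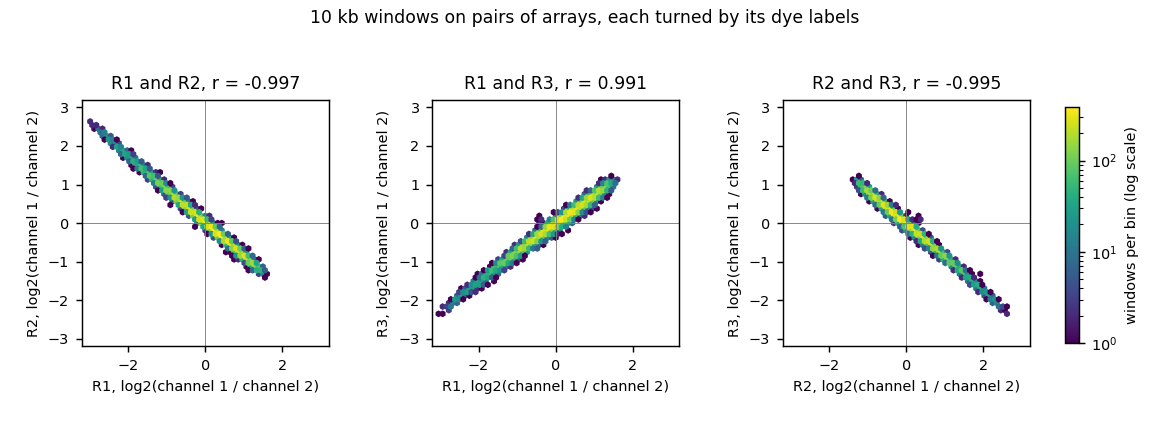
Log2 ratio of channel 1 to channel 2 in 10 kb windows for each pair of arrays, turned by the dye labels, with the number of windows per bin in colour on a log scale. Replicates 1 and 3 fall along a rising line (r = 0.991), while replicate 2 falls along a descending line against either (r = -0.997 and -0.995).

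With the arrays turned as labelled, no region of the genome could be called. Of the 12093 windows, 0 had unequal signal in the 2 channels by limma at an adjusted p of 0.05, and 0 did so at an unadjusted p of 0.05. Of the probes, 0 passed (4 at an unadjusted p of 0.05), and there were 0 domains. Without replicate 2, whose removal needs no array to be turned against its label, 8846 windows, 147960 probes and 689 domains passed.

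The patterns along the chromosomes were then read on a common axis, chosen after the data were seen, in which replicate 2 alone was turned against its dye label. P stands for the population in channel 1 of replicates 1 and 3 and channel 2 of replicate 2, and Q for the population in the other channel of each array. Which of P and Q was early stays open, and every difference given below has the same size and the opposite sign as Q over P. Because the turning used the arrays' own correlation, the likeness of the 3 arrays on this axis is not independent evidence.

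On the common axis most of the genome was unequal between P and Q. By limma with Benjamini-Hochberg adjustment, 10509 of 12093 windows passed, 5432 with more P and 5077 with more Q. Centred on the mean of the chromosome arm means in place of the median probe, 10709 passed, 6950 with more P and 3759 with more Q, so the split between the sides depends on the zero point. That centring raises each value by 0.23 and leaves the differences between regions as they are. Each fold excess of P or Q given below is relative to the median probe, so it also depends on the zero point. Chromosome 4, with 121 windows and a mean of -1.01 before it, counts in it as much as each large arm, which enlarges the shift. Of the probes, 180279 passed, 89693 with more P and 90586 with more Q. The windows reached further on the Q side. The lowest 1% of windows lay below a log2 P/Q of -2.10, and the highest 1% lay above 1.17. The middle 50% of windows lay between -0.50 and 0.49. Neighbouring 10 kb windows were alike, with a correlation of 0.976 at a distance of 10 kb, 0.513 at 100 kb and 0.071 at 1000 kb.

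Chromosome 4, the small and largely heterochromatic autosome also known as the dot chromosome, stood on the Q side along almost its whole assembled length. Its mean log2 P/Q was -1.01 ± 0.10 (SD, n = 3 arrays), a 2.01-fold excess of Q over P. Of its 121 windows 120 passed with more Q and 0 with more P. The window that did not pass, at 910001 to 920000 of chromosome 4, had a value of -0.09, within the reach of the zero point, and was looked up after its value was seen. Against the autosome arms 2L, 2R, 3L and 3R the difference was -1.01 ± 0.12, with -1.12, -1.03 and -0.88 on replicates 1, 2 and 3. An exact two-sided sign-flip permutation test over the 3 arrays gave p = 0.25, the smallest it can give. As labelled the difference was -0.32 ± 1.18 (exact permutation p = 0.75), without replicate 2 it was -1.0 ± 0.17, without replicate 1 it was 0.07 ± 1.35 and without replicate 3 it was -0.05 ± 1.52 (n = 2 each). Windows of chromosome 4 were also brighter in both dyes together, and against autosome windows of the same mean signal the difference was -0.39 ± 0.03, or -0.25 ± 0.03 when arm 3L, whose outer end was bright, was left out of those windows.

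Chromosome X also lay on the Q side, but with stretches of both kinds. Its mean log2 P/Q was -0.35 ± 0.04, and 59.0% of its 2167 windows passed with more Q against 25.0% with more P. The X minus autosome difference was -0.36 ± 0.06, with -0.42, -0.35 and -0.30 on replicates 1, 2 and 3 (exact permutation p = 0.25, the smallest possible). As labelled it was -0.12 ± 0.41 (exact permutation p = 0.75), without replicate 2 it was -0.36 ± 0.08, without replicate 1 it was 0.02 ± 0.46 and without replicate 3 it was -0.04 ± 0.54 (n = 2 each). Against autosome windows of the same mean signal it was -0.56 ± 0.10, and X windows were dimmer than those of the autosome arms.

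The 4 large autosome arms lay close to 0 as a class, at 0.00 ± 0.02. They hold 190496 of the 239717 probes in windows, so centring on the median probe largely sets this value. Arm 3R had a mean of 0.10 ± 0.03 and arm 2L of 0.09 ± 0.03, while arm 3L had -0.08 ± 0.01 and arm 2R -0.14 ± 0.01. The sides of 3L and 2R turned with the zero point, to 0.15 and 0.10 when centred on the arm means, while X (-0.12) and chromosome 4 (-0.78) stayed on the Q side. Chromosome 4 counts as an arm in that centring, and centring on the large arms alone was not run. On 3R 54.8% of windows passed with more P and 33.0% with more Q. On 2R 36.7% passed with more P and 47.3% with more Q. On 3L the tally went against the mean, with 48.5% passing with more P and 40.3% with more Q. No arm was tested against another.

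Sequence assigned to heterochromatin, which is rich in repeats and lies around the centromeres, lay on the P side. Its 299 windows had a mean log2 P/Q of 0.57 ± 0.08, a 1.49-fold excess of P, and 246 passed with more P against 29 with more Q. The right-arm part of chromosome 3 (3RHet) had 0.86 ± 0.11, with all 68 windows passing on the P side. The parts of 2R (2RHet, 0.56 ± 0.10) and of the Y (YHet, 0.66 ± 0.08) were also on the P side. The left-arm part of chromosome 3 (3LHet) was more mixed, at 0.35 ± 0.04, with 60 of its 93 windows on the P side and 23 on the Q side. Sequence placed on no chromosome (U), counted apart from these windows, had 0.74 ± 0.09 over 80 windows. With arrays centred on the arm means, the heterochromatic windows and U together had 0.84 ± 0.10. Few probes lay in the heterochromatic windows, with 2828 in all.

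**Figure D2:**
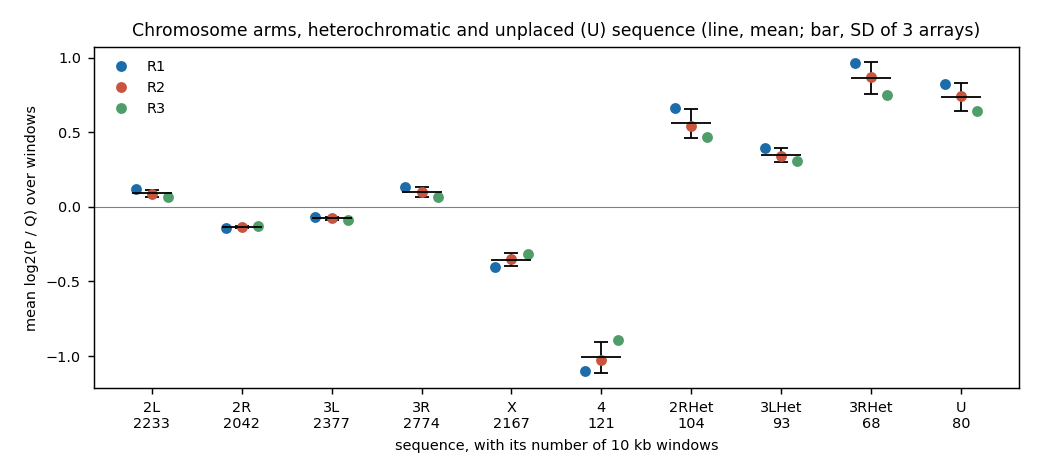
Mean log2 P/Q over 10 kb windows (vertical axis) of chromosome arms, heterochromatic sequence and unplaced sequence (U), with a point for each of the 3 arrays, a line for their mean and a bar for the SD. Chromosome 4 (-1.01) and X (-0.35) lie below 0 on each array, and 2RHet, 3LHet, 3RHet and the unplaced sequence U lie above 0, 3RHet highest of these at 0.86.

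The group set before the data were examined as pericentric was higher in P over Q than the rest of the arms. The group joins the 2 Mb at the centromere-proximal end of the assembled arms 2L, 2R, 3L, 3R and X with the heterochromatic sequence and U. Its mean was 0.24 ± 0.04 against -0.08 ± 0.00 for the distal windows. This group holds 80 windows of U, which have no known place, and 15 of the Y. The difference was 0.32 ± 0.04, with 0.35, 0.31 and 0.28 on replicates 1, 2 and 3 (exact permutation p = 0.25, the smallest possible). As labelled it was 0.11 ± 0.36 (exact permutation p = 0.75), without replicate 2 it was 0.32 ± 0.05, without replicate 1 it was -0.01 ± 0.42 and without replicate 3 it was 0.02 ± 0.47 (n = 2 each). Without U and the Y it was 0.27 ± 0.03, and without any separately named sequence, on the proximal 2 Mb of the arms alone, it was 0.15 ± 0.02. The arms did not share a direction. On X the proximal 2 Mb had 0.23 ± 0.04 against -0.40 ± 0.05 distally, on 3L 0.21 ± 0.04 against -0.10 ± 0.01, and on 2R 0.08 ± 0.03 against -0.15 ± 0.01. On 2L the 2 parts were 0.06 ± 0.02 and 0.09 ± 0.03, and on 3R the proximal part was lower, at -0.17 ± 0.01 against 0.12 ± 0.04. The differences within single arms were not tested.

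The genome fell into long tracts of like ratio. Runs of at least 3 adjacent windows that passed on the same side formed 727 domains, 381 with more P and 346 with more Q. P domains covered 50.83 Mb with a median length of 80 kb, and Q domains covered 49.13 Mb with a median of 100 kb. Domains over 200 kb numbered 71 on the P side and 74 on the Q side. Arm 3R had 14.95 Mb in P domains and 8.90 Mb in Q domains. On X the Q domains covered 12.54 Mb and the P domains 5.28 Mb. Chromosome 4 had 3 domains, each with more Q, over 1.20 Mb.

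**Figure D3:**
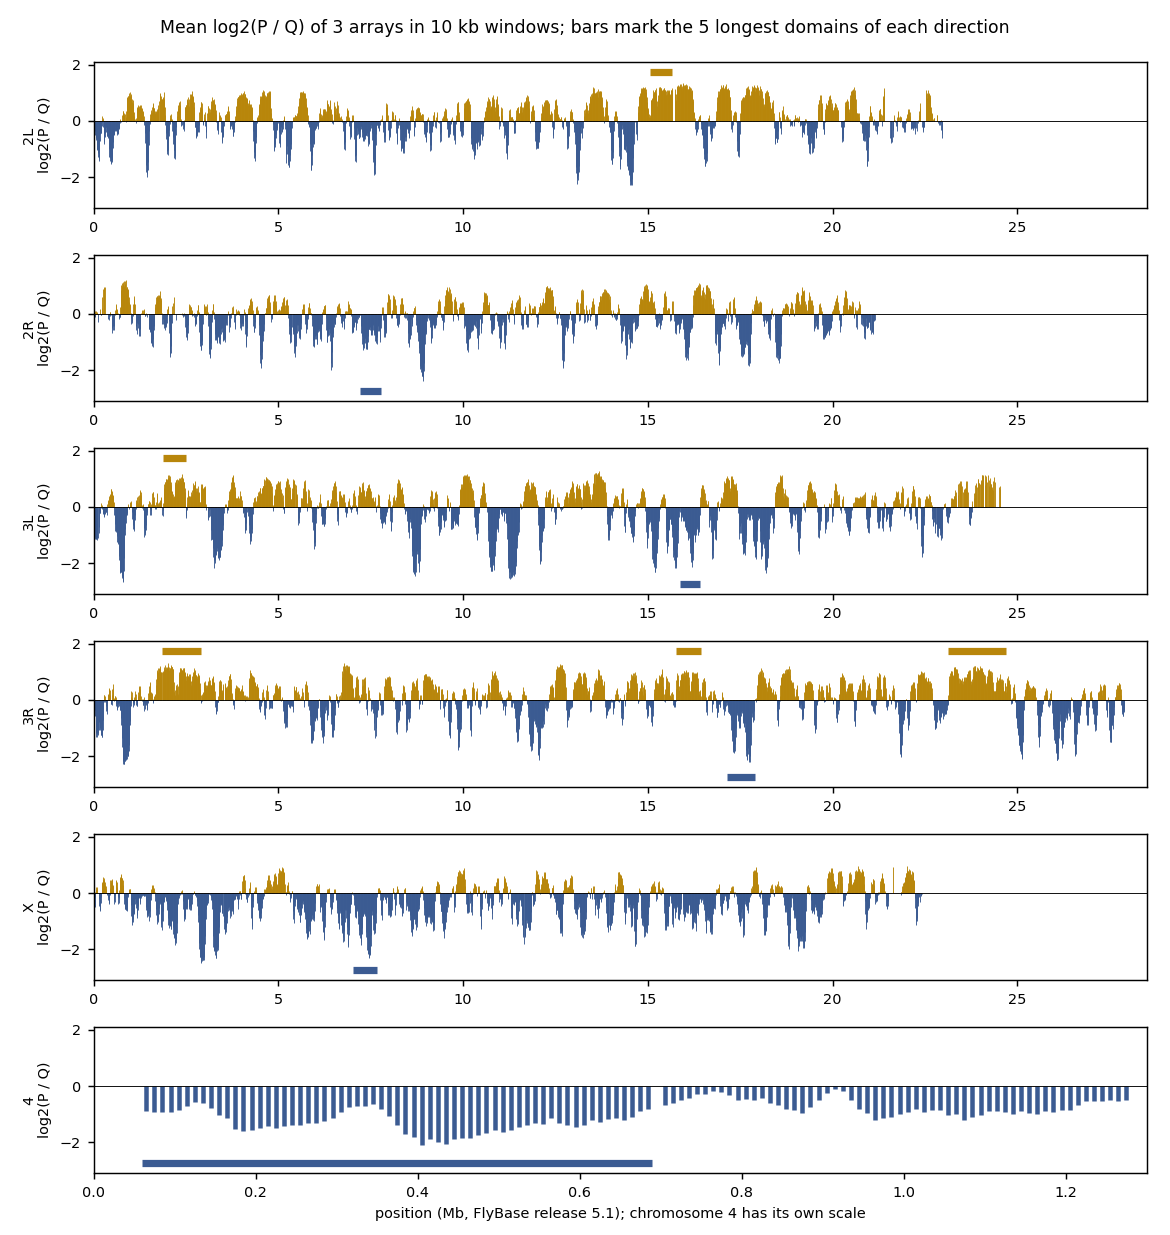
Mean log2 P/Q of the 3 arrays in 10 kb windows (vertical axis) along chromosome arms 2L, 2R, 3L, 3R, X and 4 by position in Mb on FlyBase release 5.1, with P-side windows in ochre, Q-side windows in blue and bars at the 5 longest domains of each direction. Tracts of both signs alternate on the large arms, and each window of chromosome 4 lies below 0 with arrays centred on the median probe.

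The 5 longest P domains lay on 3R, 2L and 3L (positions on FlyBase release 5.1). The longest, 3R 23130001 to 24700000, spanned 1570 kb at a log2 P/Q of 0.82 ± 0.13, a 1.76-fold excess of P. It was followed by 3R 1850001 to 2900000, of 1050 kb at 0.89 ± 0.15, which began within the proximal 2 Mb of the assembled arm. The third, 3R 15760001 to 16440000, held 0.74 ± 0.12. Domain 2L 15050001 to 15660000 had the highest mean of the 5, at 0.98 ± 0.14 or 1.97-fold, and 3L 1880001 to 2490000 had 0.82 ± 0.15.

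The 5 longest Q domains lay on 3R, 4, X, 2R and 3L. The longest, 3R 17150001 to 17890000, spanned 740 kb at -1.06 ± 0.11, a 2.09-fold excess of Q, with its lowest window at 17750001 (-2.22). On chromosome 4, 60001 to 690000 had -1.28 ± 0.13, or 2.43-fold, the lowest mean of the 5. On X, 7030001 to 7660000 had -1.19 ± 0.15. On 2R, 7220001 to 7790000 had -0.76 ± 0.10, and on 3L, 15870001 to 16410000 had -0.94 ± 0.11. What genes lie in these domains is not given here, because no annotation on release 5 of the genome was used.

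**Figure D4:**
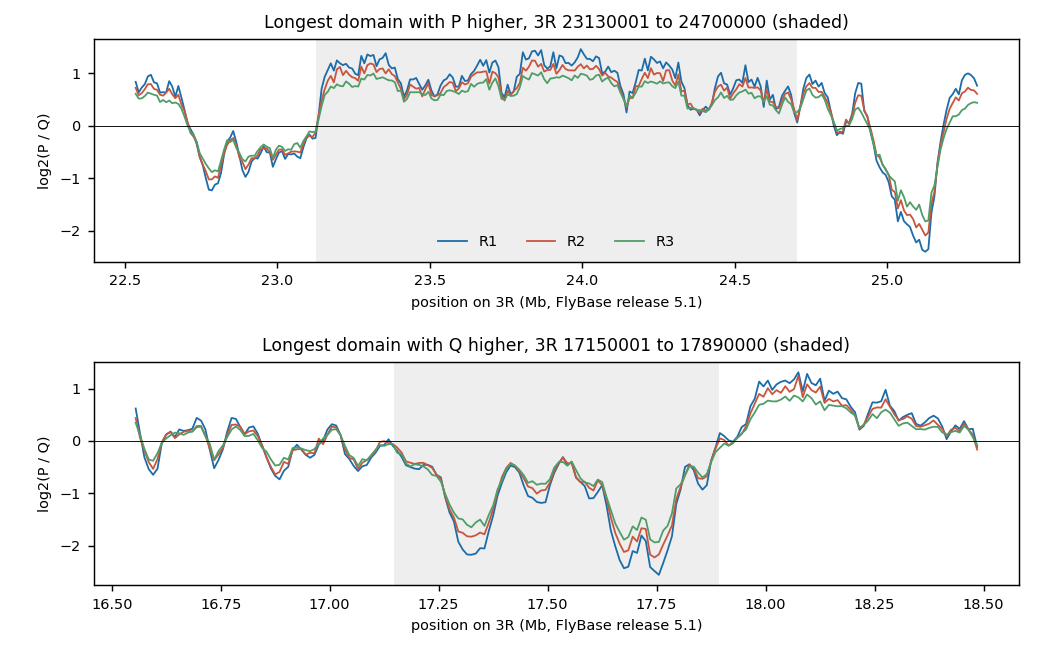
Log2 P/Q of each array (vertical axis, 1 line per replicate) in 10 kb windows across the longest domain of each direction and its flanks on 3R, with the domain shaded. The 3 lines rise and fall at the same places, with replicate 1 farthest from 0 and replicate 3 nearest in both domains (0.94, 0.82 and 0.69 in the P domain, -1.18, -1.05 and -0.96 in the Q domain).

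The ratio also followed base composition, but weakly, in a test that was not in the first plan. Across the 12093 windows the Spearman correlation of log2 P/Q with the GC content of the probes was -0.11, against -0.04 to 0.05 in the central 95% of 10000 circular shifts of the genome (two-sided permutation p = 1e-04, the smallest they can give). On single arms it ran from -0.20 on 3R and -0.19 on 2L to -0.07 on 2R. Windows are not independent replicates, and these are correlations across positions.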

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

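Settings called common axis, with replicate 2 turned, and those matched on signal or GC, without U and the Y, centred on arm means or without pooled spread were chosen after the data were seen. The direction of replicate 2 changed the results most. As labelled, 0 windows, 0 probes and 0 domains passed under each planned setting except 1, and turning replicate 2 gave 10509 windows, 180279 probes and 727 domains. Leaving out 1 replicate as labelled gave 0 to 8846 windows, 0 to 147960 probes and 0 to 689 domains, the highest each time without replicate 2. The lowest correlation of a pair, -0.997 as labelled, reversed to 0.991 with replicate 2 turned. Differences between chromosome classes as labelled had exact permutation p-values of 0.75 or 1 with all 3 arrays, and 3 arrays cannot give a p under 0.25. Leaving out 1 replicate as labelled, chromosome 4 ran from -1.0 to 0.07, X from -0.36 to 0.02 and the pericentric difference from -0.01 to 0.32, each near 0 and turned in sign without replicate 1. With equal weight for both dye orientations as labelled, chromosome 4 was -0.52 (from -0.32), X -0.20 (from -0.12) and the pericentric difference 0.17 (from 0.11). The SDs over arrays were larger than these moves, at 1.18, 0.41 and 0.36. On the common axis the windows that passed numbered 19665 at 5 kb, 4463 at 25 kb and 2355 at 50 kb, as the number of windows tested differs with their size. The domains numbered 1132 at 5 kb and 477 at 25 kb, where the shortest run of 3 windows also differs in length. Domains were not computed with arrays centred on arm means. The 16 other window settings gave counts within 1.5 times the 10509, and the split moved to 6950 with more P and 3759 with more Q when arrays were centred on arm means. Chromosome 4 against the autosome arms, -1.01, was -0.82 in the authors' deposited ratios and -0.39 against windows of the same mean signal (-0.25 without arm 3L), and X, -0.36, was -0.56 against windows of the same signal. The pericentric difference, 0.32, was 0.39 with the proximal 1 Mb, 0.22 with 4 Mb, 0.26 in the authors' deposited ratios, 0.27 without U and the Y and 0.15 without U and the named heterochromatic sequence. The cause of these shifts on the common axis was not tested, and none of them changed the sign of the chromosome 4, X or pericentric difference. The means of arms 3L and 2R did change sign with arrays centred on arm means. Leaving out 1 array on the common axis gave -1.07 to -0.95 for chromosome 4, -0.38 to -0.32 for X and 0.30 to 0.33 for the pericentric difference. Gene density and gene lists were not run. No paired analysis was possible because there was 1 group. Over 99.8% of probes were above background in both dyes, which does not show whether signal left over from background changed the ratios.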

Other observations

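In this part the tests of replicate 2, of normalisation for the size of the ratios, of dye bias, of the loess correction and of matching on GC content or mean signal, with or without 3L, were chosen after the results were seen, and values are on the common axis (log2 P/Q, mean ± SD of 3 arrays). Motifs known from promoters were searched in the sequences of all probes, since the files hold probe sequences but no gene names. This search was not in the first plan. Whether a probe lay at a promoter was not known. The DNA replication-related element TATCGATA, bound by the factor DREF at promoters of many replication and growth genes, occurred in 387 probes, which fell in 376 windows. These windows had a mean of -0.24 ± 0.03, a difference of -0.18 from the genome mean (permutation p = 2e-04 over 10000 circular shifts, adjusted p = 0.0016 over 8 motif classes), and 208 passed with more Q against 122 with more P. The same bases in reverse order, ATAGCTAT, gave a difference of -0.05 over 185 windows (permutation p = 0.37), a control added later. The GAGA repeat GAGAGAGA, bound by GAGA factor at many promoters, occurred in 521 probes and gave -0.11 over 509 windows (permutation p = 0.0018, adjusted p = 0.0072), with 242 windows on the Q side and 204 on the P side. Against windows of the same mean signal the differences were -0.18 for the DNA replication-related element and -0.07 for the GAGA repeat. The GAGA bases in reverse order are the same repeat shifted by a base, so they cannot serve as such a control. They occurred in 606 probes, which were not tested. The other 6 classes, protein motifs read from translated probes, had 1 to 4 probes each and cannot speak for their gene families, although 2 of them passed the same test, the C2H2 zinc finger linker with 1 probe (permutation, adjusted p = 0.0293) and the DEAD box helicase with 3 (permutation, adjusted p = 0.0408). Their differences were 0.29 (homeodomain), -2.02 (C2H2 zinc finger linker), -0.14 (protein kinase), 0.35 (trypsin-like serine protease), 0.15 (cytochrome P450) and -0.95 (DEAD box helicase).

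The summaries in this paragraph were not planned before the data were examined. The outer 500 kb of the arms lay on the Q side on 2L (-0.68 ± 0.08, 44 of 50 windows with more Q), 2R (-0.29 ± 0.07), 3R (-0.25 ± 0.02) and 3L (-0.21 ± 0.01), and slightly on the P side on X (0.08 ± 0.01). Raised by 0.23, as centring on the arm means with chromosome 4 among them does, the ends of 3L, 3R and 2R would lie near 0, with no clear side. The steepest change between neighbouring 30 kb stretches was at 3R 10230001, where the ratio rose from -1.06 to 0.22, a step of 1.28 ± 0.25 against a median step of 0.21. At 3L 22390001 it went from -0.10 to -1.38, and at 2L 14610001 from -1.66 to -0.45. Of the 121 windows lowest in P over Q, 97 lay on the large autosome arms, 24 on X and 0 on chromosome 4, so chromosome 4 was low along its length without holding the lowest windows. Among 1 Mb stretches with at least 50 windows, the mean signal of both dyes was highest at the outer end of 3L, with a log2 signal of 11.41 in its first Mb against 10.22 over the autosome arms, 10.94 on chromosome 4 and 9.61 on X. Probes differ in their response, so these levels are given as values only. DNA copy number could differ between these regions as well, which would also bear on the differences matched on signal (-0.39 for chromosome 4, -0.56 for X), and it was not tested, since no unselected DNA was used here.

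Turned by the dye labels, replicate 2 ran against replicates 1 and 3 along the whole genome. Noise on that array is argued against by its correlation with the others, whose size was at least 0.995 over windows. After turning replicate 2 each pair of arrays had a correlation of at least 0.989 on each large arm and on chromosome 4, but correlations this strong before turning fix that outcome, so it decides nothing. Channel or dye labels that do not follow the populations on all arrays stay open, as does whether replicate 2 or replicates 1 and 3 together are turned, and no biological explanation was tested. Of the 4 sign patterns of the 3 arrays, the labelled one gave 0 windows and the highest other gave 10509. All 4 reach a count of 0, so the comparison says nothing about chance, and 4 patterns are too few for a share under 0.05 in any case.

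The 3 arrays differed in the size of their ratios, with an SD over windows of 0.84 on replicate 1, 0.73 on replicate 2 and 0.62 on replicate 3. None of the 5 kinds of processing compared removed this difference. The SD of replicate 3 over that of replicate 1 was 0.741 in the main values and reached at most 0.836, with normexp. The authors' deposited ratios gave 0.808. Only these 2 handled background otherwise than the main values. Background and dye normalisation is argued against as the whole cause only for the kinds compared, and it may account for part. Signal left over from background stays open, since the slope of replicate 3 on replicate 1 was higher by 0.067 among the brightest 48258 probes than among the dimmest 48259, between the bounds set for and against it. No biological explanation was tested, because the arrays are of 1 group.

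Chromosome 4 stood apart from the autosome arms by -1.01 ± 0.12. GC content is argued against, since the difference was -1.09 ± 0.14 against windows of the same GC content. Dye bias as the whole cause is argued against, since the difference was -0.88 on replicate 3, where P carried the other dye. Only replicate 3 had that orientation and its difference was the smallest, so a dye share in part is not excluded. Brightness stays open: against autosome windows of the same mean signal the difference was -0.39 ± 0.03 (-0.25 ± 0.03 without the windows of 3L), as a link with brightness would give, while a loess correction for the brightness of single probes left -0.91 ± 0.09. Mean signal is not independent of the ratio, because across autosome windows the log2 signal of Q varied more (SD 0.69) than that of P (0.45) and mean signal and ratio had a correlation of -0.42. Matching may thus remove part of a true difference, and DNA copy number was not measured. X had dim windows yet a ratio on the Q side (-0.56 when matched). Within X, however, mean signal and ratio had a correlation of -0.52, so brighter windows lay further to the Q side there too. With copy number unknown, X therefore does not decide the question.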
